A study of Caenorhabditis elegans with 12 samples.

How the data were processed

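Polyadenylated RNA was measured in whole C. elegans larvae at the fourth larval stage. Per the labels' protocols, about 1000 animals per culture were synchronised by bleaching and fed HT115 bacteria with an empty vector. RNA was extracted with Qiazol and column purification, treated with DNase, had an integrity number of 10 and was made into stranded, polyA-selected libraries with an NEB kit. The labels give 4 strains, N2, itr-1(sa73), nuo-6(qm200) and the double mutant, with 3 biological replicates each, and do not say what a replicate number shares across strains. The values deposited by the authors are TPM, length-corrected shares of a library's transcripts, for 46926 genes in 12 libraries. Each library has the same sum, so a change in abundant genes shifts all others. The genome build is WBcel235 per the submitters' processing notes. The aligner, the counting tool and the annotation version are not given in the sources used here. All 46926 gene identifiers were found in the reference annotation of WBcel235, from which gene names and positions were taken. TPM keeps no depth, so no counting interval or detection floor is given, and the number of libraries sets the precision. No 2 libraries held identical values. How multi-mapped reads were counted is not given, so genes with near-identical copies (major sperm proteins, vitellogenins, collagens, abu and pqn genes) are uncertain as single genes.

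From these values, log2(TPM + 1) was computed for the 15230 genes with at least 1 TPM in at least 3 libraries. One linear model over all 12 libraries was fitted per gene with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with trend, 8 residual and 2.85 prior degrees of freedom), so that all strains share one estimate of the spread. The 5 comparisons were nuo-6 against N2, itr-1 against N2, double mutant against nuo-6, double mutant against itr-1, and the interaction. Adjusted p is limma's with Benjamini-Hochberg adjustment over all genes tested within a comparison, two-sided, and a gene changed where it was under 0.05. In total 34 gene lists were tested with camera, limma's test of a list against all other genes, with a preset correlation of 0.01 between genes and again with a correlation estimated from the residuals, adjusted over the 34 lists of a comparison. Counts of list members are given as adjusted over all genes and as adjusted over the list alone. The lists cover mitochondrial and stress programmes, metabolism, cytoskeleton and calcium signalling, protein synthesis and turnover, defence, cuticle and moulting, germ cells and tissues. The main model, the comparisons, the alternatives tried, the lists and the rule for named genes were fixed before the data were examined.

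Named genes are the 8 largest rises and 8 largest falls in the first 3 comparisons and the 5 largest each way in the other 2, among changed genes with a name, at least 5 TPM on average in the higher group and no overlap between the libraries compared, with at most 2 per family. To these were added itr-1 and nuo-6 in every comparison and the 4 members of each list with the smallest adjusted p. The model was tested on simulated data with 200 genes changed by known folds. For nuo-6 against N2, simulated over 14283 genes, it recovered 46.3% of genes changed 1.5-fold, 77.6% of those changed 2-fold and 90.9% of those changed 4-fold, and 4 of 147 called genes were unchanged. For the interaction, simulated over 14309 genes, it recovered 28.4%, 53.7% and 83.3%, and 10 of 120 called genes were unchanged. The simulated noise was independent between genes, without a shift or replicate effect shared by a library. In the data far more genes changed (7968 of 15230 in nuo-6 against N2), which alters the adjusted p. These rates therefore do not carry over to the data. Alternatives were pseudocounts of 0.1 and 0.5, no filter and a filter of 5 TPM, median-of-ratios scaling, quantile normalization, a fit of only the groups compared, array weights, eBayes with the robust option or without trend, a fold minimum of 2, the replicate number as a term, and the omission of each library. After the data were seen, 3 more were added, namely the omission of all libraries numbered 2, TPM re-closed to its full sum without cytosolic ribosomal protein genes, and the stage score as a covariate. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.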

Results

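RNA was measured in whole larvae of the nematode Caenorhabditis elegans at the fourth larval stage, in 12 libraries from 4 strains with 3 biological replicates each. The strains were the laboratory wild type N2, a mutant of nuo-6, which encodes a subunit of mitochondrial complex I, a mutant of itr-1, which encodes the inositol trisphosphate (InsP3) receptor that releases calcium from the endoplasmic reticulum, and the double mutant of both. Values were TPM, a length-corrected share of each library's transcripts, for 46926 genes, and 13879 to 14902 genes per library had at least 1 TPM. The read depth is unknown, because TPM keeps no depth. Gene levels are given as mean TPM ± SD (n = 3 libraries), and changes as log2 fold ± SE between groups of 3 libraries on the log2(TPM + 1) scale, which understates the change of genes with low TPM. The study's title asks whether InsP3 receptor signalling mediates the long life that mitochondrial stress brings, through actomyosin and mitochondrial dynamics.

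The mutated genes were read first. The itr-1 transcript (WBGene00002173, chromosome IV, 7675174 to 7696930, WBcel235) stood at 21.2 ± 3.18 TPM in N2, 27.1 ± 4.2 in the itr-1 mutant, 30.3 ± 2.74 in the nuo-6 mutant and 33.7 ± 1.21 in the double mutant. The nuo-6 transcript (WBGene00012166, chromosome I, 7068116 to 7069186) stood at 324 ± 7.18, 280 ± 13.5, 392 ± 15.1 and 309 ± 19.3 TPM in the same order. Both alleles are known as changes of single amino acids, so these levels do not check the strain labels. Over the 15230 genes tested, the first principal component held 53.9% and the second 19.2% of the variance, and libraries of one strain correlated with each other at 0.975 to 0.992 across genes. A stage score, the mean log2(TPM + 1) of 30 oocyte and early embryo genes and chosen after the data were seen, was 3.34 to 4.17 in the N2 libraries, 4.79 to 5.90 in itr-1, 4.56 to 4.78 in nuo-6 and 4.38 to 5.65 in the double mutant.

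The first comparison, nuo-6 mutant against N2, asks which transcripts differ when complex I is impaired. Genes of the mitochondrial unfolded protein response (UPRmt), of glycolysis, oxidative stress and detoxification were higher in the mutant, while ribosomal protein and proteasome genes were lower. None of these list calls held with an estimated correlation (adjusted p = 0.272 to 0.438). The mitochondrial thioredoxin gene trx-2 (WBGene00007099, chromosome V, 10314671 to 10315294) rose from 95.8 ± 2.75 to 191 ± 5.87 TPM, a log2 fold of 0.99 ± 0.05 (SE, n = 3 per group, adjusted p = 1.78e-07). The lactate dehydrogenase gene ldh-1 (WBGene00002262, chromosome II, 11724204 to 11726533) rose from 69.7 ± 4.61 to 191 ± 3.83 TPM (1.44 ± 0.05, adjusted p = 2.42e-08). The beta-tubulin gene tbb-6 (WBGene00006539, chromosome V, 12261531 to 12263368) rose from 3.54 ± 0.708 to 116 ± 7.31 TPM (4.69 ± 0.10, adjusted p = 2.74e-10), and the lysozyme gene ilys-5 (WBGene00017691, chromosome X, 6533490 to 6536840) fell from 1040 ± 163 to 49.3 ± 13.6 TPM (-4.40 ± 0.32, adjusted p = 1.88e-06). In all, 7968 genes (52.3% of those tested) changed, 5676 up and 2292 down, and the libraries of both groups did not overlap in 10054 of the 15230 tested, where chance gives 10%. Overlap was read on unscaled TPM, here and in the later comparisons. The median-of-ratios factors of N2 (0.88 to 0.944) and nuo-6 libraries (1.005 to 1.03) did not overlap either, so a library-wide shift can add to such counts. Median-of-ratios scaling lowered the median fold of all genes by 0.14 and gave 3983 rises and 3504 falls, and quantile normalization gave 3176 and 4297. Shifts of gene lists are therefore given below as the list's median minus the median of all tested genes, which was 0.18 here.

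Of the 24 UPRmt genes, 20 rose and 1 fell (20 and 1 adjusted over the list alone, 19 and 2 with median-of-ratios scaling). The shift was 0.45 (camera adjusted p = 1.01e-05, adjusted p = 0.295 with an estimated correlation). Besides trx-2, the mitochondrial co-chaperone gene dnj-10 rose by 1.16 ± 0.07, the import translocase gene timm-17B.1 by 0.79 ± 0.06 and atfs-1, the transcription factor of this response, by 0.99 ± 0.08. Glycolysis and gluconeogenesis genes rose in 19 of 24 cases and fell in 1 (21 and 1 adjusted over the list alone). The shift was 0.36 (camera adjusted p = 1.31e-05, adjusted p = 0.438 with an estimated correlation). The aldolase gene aldo-1 went from 186 ± 13.6 to 569 ± 2.69 TPM (1.61 ± 0.06, adjusted p = 2.42e-08). Among 16 targets of the hypoxia factor HIF-1, 11 rose and 2 fell (11 and 2 adjusted over the list alone, 8 and 4 with median-of-ratios scaling), shifted by 0.42 (camera adjusted p = 0.0339, adjusted p = 0.438 with an estimated correlation). That call was lost with the replicate number as a term in the model (camera adjusted p = 0.0578, the highest of 0.0046 to 0.0578 over 22 alternatives). It was also lost without all libraries numbered 2, an omission chosen after the data were seen (adjusted p = 0.0935). The targets that rose included ldh-1 and the sulfide oxidoreductase gene sqrd-1 at 2.06 ± 0.12. Nuclear genes of complex I rose in 33 of 35 cases (34 and 1 adjusted over the list alone, 18 and 1 with median-of-ratios scaling) and shifted by 0.17 (camera adjusted p = 2.64e-07, adjusted p = 0.417 with an estimated correlation). The gene nduf-6 was at 0.57 ± 0.04 and nuo-2 at 0.52 ± 0.04. Of the 22 genes of mitochondrial dynamics and mitophagy, 18 rose and 0 fell (18 and 0 adjusted over the list alone), shifted by 0.25 (camera adjusted p = 8.65e-04, adjusted p = 0.272 with an estimated correlation). They included drp-1, the fission dynamin, at 0.71 ± 0.06, and sqst-1, the p62 autophagy receptor, at 1.33 ± 0.13. The mitochondrial ribosome list had 46 rises among 70 genes (47 and 2 adjusted over the list alone), but 15 and 6 with median-of-ratios scaling, and its shift was 0.03.

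Of 21 targets of the longevity factor DAF-16, 15 rose and 1 fell (15 and 1 adjusted over the list alone). The shift was 0.79 (camera adjusted p = 0.00117, adjusted p = 0.295 with an estimated correlation). The rises included sod-3, a mitochondrial superoxide dismutase, from 1.98 ± 0.23 to 18.2 ± 0.207 TPM (2.69 ± 0.09), and the metallothionein gene mtl-1 at 4.48 ± 0.24. Oxidative stress genes and targets of SKN-1, a regulator of antioxidant genes, counted 21 rises and 1 fall among 31 (21 and 1 adjusted over the list alone, 14 and 2 with median-of-ratios scaling, shift 0.17, camera adjusted p = 0.00284, adjusted p = 0.272 with an estimated correlation). Detoxification genes counted 106 rises and 19 falls among 176 (106 and 21 adjusted over the list alone, shift 0.42, camera adjusted p = 0.00105, adjusted p = 0.438 with an estimated correlation). The cytochrome P450 gene cyp-14A4 was at 4.24 ± 0.15 and the cadmium-responsive gene cdr-2 at 3.37 ± 0.15. Cytosolic ribosomal protein genes fell in 79 of 81 cases (0 and 79 adjusted over the list alone, shift -0.52, camera adjusted p = 3.2e-36, adjusted p = 0.272 with an estimated correlation). The gene rpl-28 fell from 3470 ± 36.9 to 2520 ± 67 TPM. The list's summed share of the TPM was 28.2% to 29.4% in N2 libraries and 22.4% to 22.7% in nuo-6 libraries. Proteasome genes fell in 31 of 33 cases (0 and 33 adjusted over the list alone, shift -0.52, camera adjusted p = 5.55e-19, adjusted p = 0.295 with an estimated correlation). The gene pbs-4 was at -0.41 ± 0.04. The unfolded protein response of the endoplasmic reticulum counted 3 rises and 13 falls among 28 (3 and 14 adjusted over the list alone, shift -0.31, camera adjusted p = 4.05e-05, adjusted p = 0.272 with an estimated correlation). The translocon gene sec-61.A was at -0.64 ± 0.04. Heat shock genes went both ways, with 6 rises and 9 falls among 25 (6 and 9 adjusted over the list alone, shift -0.47, camera adjusted p = 0.0217, adjusted p = 0.741 with an estimated correlation). The small heat shock gene sip-1 was at 2.36 ± 0.41 and the chaperone gene hsp-1 at -0.38 ± 0.06. The list's call was lost with median-of-ratios scaling (adjusted p = 0.0984), quantile normalization (0.306), the stage score as a covariate (0.0583) and without N2 replicate 1 (0.0759), of 4.97e-04 to 0.306 over 22 alternatives. Oocyte and early embryo genes rose in 19 of 30 cases and fell in 0 (21 and 0 adjusted over the list alone, 12 and 0 with median-of-ratios scaling, shift 0.85, camera adjusted p = 0.0352, adjusted p = 0.787 with an estimated correlation). The higher stage score of the nuo-6 libraries (4.56 to 4.78 against 3.34 to 4.17) is the mean of these same genes and no separate evidence. The call of this list was lost without N2 replicate 1 (adjusted p = 0.0825) or 3 (0.0787) and without nuo-6 replicate 2 (0.0735) or 3 (0.0524), of 5.11e-04 to 0.0825 over 22 alternatives.

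The non-muscle actomyosin list and the list of InsP3 and calcium signalling did not pass as groups. Of 58 non-muscle actomyosin genes, 16 rose and 5 fell (15 and 5 adjusted over the list alone, 5 and 14 with median-of-ratios scaling; camera adjusted p = 0.69, adjusted p = 0.909 with an estimated correlation). Their median was 0.10 while camera's direction was downward. Of 42 InsP3 and calcium signalling genes, 16 rose and 4 fell (16 and 4 adjusted over the list alone, 12 and 8 with median-of-ratios scaling, camera adjusted p = 0.256, adjusted p = 0.792 with an estimated correlation). This list passed with the stage score as a covariate, chosen after the data were seen (adjusted p = 0.0248, median 0.21, against 0.118 to 0.788 over 22 alternatives). The protein kinase C gene tpa-1 stood at 0.87 ± 0.07. Of 54 fatty acid and lipid genes, 20 rose and 12 fell (21 and 14 adjusted over the list alone, 11 and 18 with median-of-ratios scaling, camera adjusted p = 0.318, adjusted p = 0.787 with an estimated correlation). Within that list the desaturase gene fat-7 fell from 26.6 ± 4.04 to 3.43 ± 0.769 TPM (-2.64 ± 0.17) and the acyl-CoA dehydrogenase gene acdh-2 rose from 2.27 ± 1.3 to 45.5 ± 7.87 TPM (3.89 ± 0.23). Innate immunity genes, 40 up and 10 down of 85 (40 and 11 adjusted over the list alone, 29 and 16 with median-of-ratios scaling), did not pass either (camera adjusted p = 0.502, adjusted p = 0.885 with an estimated correlation). They passed with the stage score (adjusted p = 0.0115, median 0.51, against 0.0649 to 0.672).

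The second comparison, itr-1 mutant against N2, asks which transcripts differ when the InsP3 receptor is impaired on its own. Genes with large folds included ech-9, ugt-18 and clec-60, which were higher in the mutant, and acdh-1, hphd-1, gst-4 and gst-10, which were lower. The enoyl-CoA hydratase gene ech-9 (WBGene00001158, chromosome IV, 10233310 to 10235329) rose from 0.735 ± 0.23 to 98.2 ± 20.9 TPM, a log2 fold of 5.82 ± 0.21 (SE, n = 3 per group, adjusted p = 7.12e-08). The UDP-glucuronosyltransferase gene ugt-18 rose from 0.108 ± 0.0524 to 45.5 ± 6.7 TPM (5.38 ± 0.16, adjusted p = 1.75e-08), and the C-type lectin gene clec-60 rose by 4.35 ± 0.19. The acyl-CoA dehydrogenase gene acdh-1 of the propionate shunt (WBGene00016943, chromosome I, 6497436 to 6499560) fell from 460 ± 172 to 40.7 ± 10.6 TPM (-3.42 ± 0.32, adjusted p = 2.93e-05), and hphd-1 of the same pathway fell from 161 ± 37.3 to 39.3 ± 3.31 TPM (-1.98 ± 0.15). The glutathione S-transferase genes gst-4 and gst-10 fell by 1.87 ± 0.13 and 2.40 ± 0.15. In all, 6109 genes (40.1%) changed, 4413 up and 1696 down, and the groups' libraries did not overlap in 7743 of the 15230 tested, where chance gives 10%. Median-of-ratios scaling lowered the median fold of all genes by 0.13 and gave 2792 rises and 3027 falls, and quantile normalization gave 2121 and 3032. With the stage score as a covariate, chosen after the data were seen, 1964 genes passed.

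Of 35 nuclear complex I genes, 0 rose and 20 fell (0 and 22 adjusted over the list alone, 0 and 31 with median-of-ratios scaling). The shift was -0.28 against a median of all genes of 0.14 (camera adjusted p = 2.87e-10, adjusted p = 0.431 with an estimated correlation). An example was ndub-3, which went from 445 ± 5.82 to 369 ± 14.1 TPM (-0.27 ± 0.04, adjusted p = 7.71e-04). Genes encoded by mitochondrial DNA fell in 8 of 12 cases (0 and 9 adjusted over the list alone, shift -0.57, camera adjusted p = 6.24e-07, adjusted p = 0.431 with an estimated correlation), and mitochondrial ribosome genes in 15 of 70 with 1 rise (1 and 8 adjusted over the list alone, 51 falls with median-of-ratios scaling, shift -0.25, camera adjusted p = 1.12e-07, adjusted p = 0.431 with an estimated correlation). Muscle sarcomere genes counted 4 rises and 21 falls among 49 (4 and 24 adjusted over the list alone, 3 and 36 with median-of-ratios scaling, shift -0.27, camera adjusted p = 6.56e-09, adjusted p = 0.151 with an estimated correlation). The troponin gene tnt-2 was at -0.42 ± 0.04, unc-27 at -0.41 ± 0.04 and pat-10 at -0.43 ± 0.05. Calsequestrin, the calcium-binding protein of muscle reticulum, had its gene csq-1 at 297 ± 6.02 TPM in N2 and 228 ± 0.942 in itr-1 (-0.38 ± 0.05). One-carbon and propionate genes counted 1 rise and 10 falls among 25 (1 and 10 adjusted over the list alone, 0 and 15 with median-of-ratios scaling, shift -0.29, camera adjusted p = 2.02e-06, adjusted p = 0.1 with an estimated correlation), among them the serine hydroxymethyltransferase gene mel-32 at -0.52 ± 0.04. Of 21 DAF-16 targets, 13 rose and 0 fell (13 and 1 adjusted over the list alone, shift 0.44, camera adjusted p = 0.00989, adjusted p = 0.431 with an estimated correlation), and without itr-1 replicate 3 camera's adjusted p was 0.0503, the highest of 2.09e-04 to 0.0503 over 22 alternatives. The UPRmt list did not pass, with 5 rises and 3 falls (5 and 3 adjusted over the list alone, camera adjusted p = 0.293, adjusted p = 0.758 with an estimated correlation), although with median-of-ratios scaling it counted 1 rise and 11 falls and passed at 0.031, the lowest of 0.031 to 0.997 over the alternatives. Innate immunity genes counted 37 rises and 14 falls among 85 and did not pass (37 and 15 adjusted over the list alone, camera adjusted p = 0.559, adjusted p = 0.87 with an estimated correlation). They passed with quantile normalization (adjusted p = 0.0362, the lowest of 0.0362 to 0.979) and with the stage score as a covariate (adjusted p = 4.9e-05). Detoxification genes did not pass, with 52 rises and 31 falls among 176 (56 and 31 adjusted over the list alone, 43 and 41 with median-of-ratios scaling, camera adjusted p = 0.492, adjusted p = 0.831 with an estimated correlation).

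Germ cell and moulting genes also differed, beside the higher stage score of the itr-1 libraries (4.79 to 5.90 against 3.34 to 4.17). All 30 oocyte and early embryo genes, whose mean is the stage score itself, rose (shift 1.47, camera adjusted p = 1.77e-06, adjusted p = 0.682 with an estimated correlation), among them the oocyte regulator lin-41 at 1.54 ± 0.20. Sperm genes counted 57 rises and 3 falls among 80 (59 and 4 adjusted over the list alone, shift 0.90, camera adjusted p = 2.74e-05, adjusted p = 0.731 with an estimated correlation). The gene msp-113 was at 1.76 ± 0.28, although major sperm protein copies are near-identical and their separate values are uncertain. Moulting and apical matrix genes went both ways, 18 up and 26 down of 69 (19 and 29 adjusted over the list alone, shift -0.34, camera adjusted p = 0.00202, adjusted p = 0.71 with an estimated correlation). The gene grl-21 was at 2.65 ± 0.18. The call of the list was lost with quantile normalization (adjusted p = 0.0573, the highest of 2.78e-04 to 0.0573). Collagen genes of the cuticle counted 64 rises and 39 falls among 135 (69 and 41 adjusted over the list alone, camera adjusted p = 0.9, adjusted p = 0.966 with an estimated correlation). They passed upward with quantile normalization (adjusted p = 0.00271, the lowest of 0.00271 to 1). With the stage score as a covariate, the calls of the moulting, sperm and mitochondrial ribosome lists and of ndub-3 and msp-113 were lost, and the oocyte list, from which the score is made, cannot be read. The calls of the complex I, mtDNA, muscle and one-carbon lists held, with medians that went from -0.14 to -0.072, from -0.43 to -0.24, from -0.13 to -0.081 and from -0.15 to -0.12.

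Sperm genes that went against their list included msp-19. The major sperm protein gene msp-19 (WBGene00003426, chromosome IV, 5260589 to 5260972) fell to 3.79, 5.02 and 3.79 TPM in the 3 itr-1 libraries, against 57.7 to 175 TPM in the other 9 (-3.78 ± 0.30, adjusted p = 1.14e-05). Its neighbours, chosen after their values were seen, moved with it. F36H12.5 (WBGene00018121) and F36H12.4 (WBGene00018120), at 8.87 to 18.7 and 8.36 to 22.2 TPM in the other libraries, and the pseudogene WBGene00018127 were listed at 0 in all 3 itr-1 libraries. The stretch that holds these 4 genes spans 9038 bp of chromosome IV, 5260589 to 5269626, and lies 2405548 bp from itr-1. On either side ttbk-2.1 was at -1.99 and F36H12.9 at -1.04 in itr-1 against N2, F36H12.10 was at 0.27 and F36H12.3 at 0.71, and within it the major sperm protein pseudogene WBGene00003445 was at 1.21. In the double mutant the 4 genes were at a median of -0.16 against nuo-6.

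**Figure D1:**
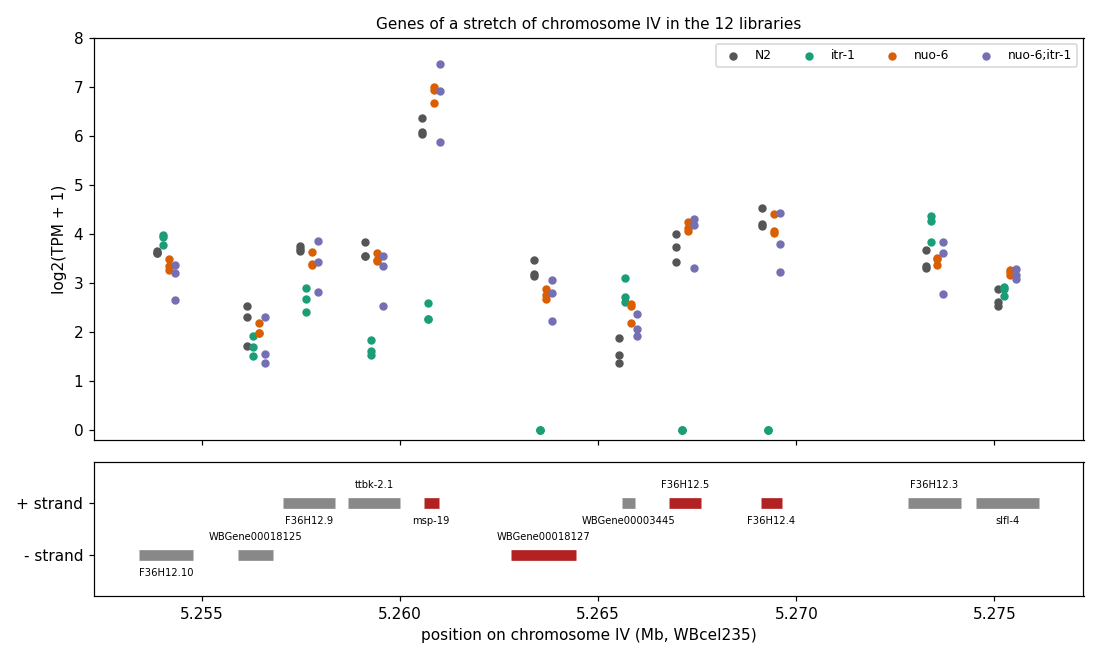
Expression by position around msp-19 on chromosome IV, as log2(TPM + 1) in each of the 12 libraries, above a map of the annotated genes by strand. The 4 genes drawn in red fell in the itr-1 libraries, where 3 of them were listed at 0.

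**Figure D2:**
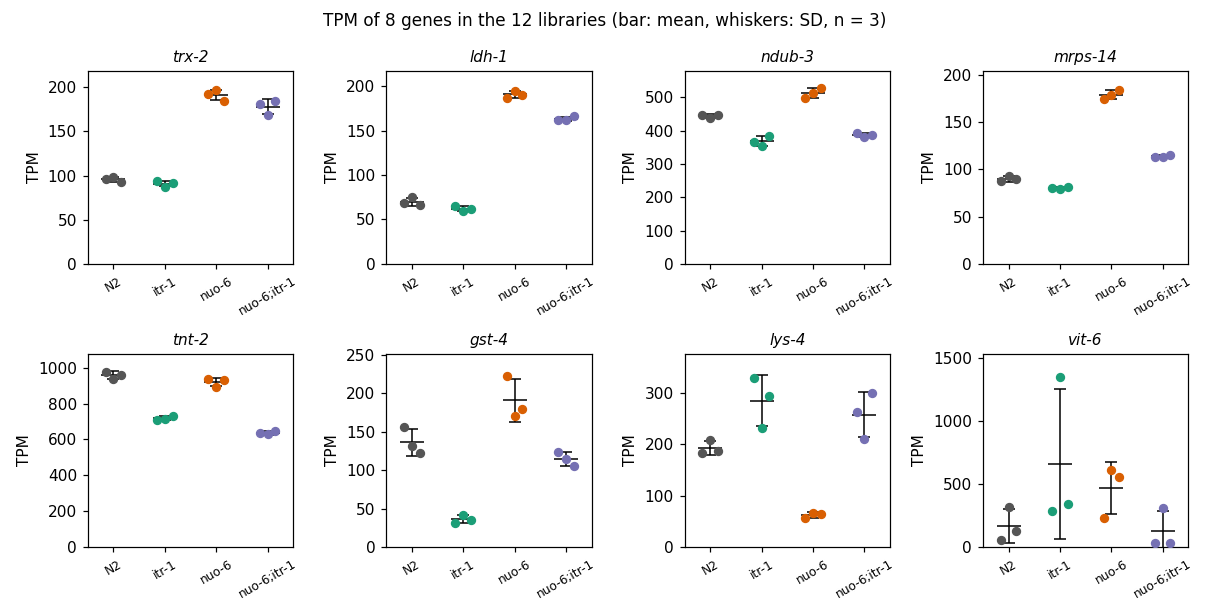
TPM of 8 genes (trx-2, ldh-1, ndub-3, mrps-14, tnt-2, gst-4, lys-4 and vit-6) in each library of the 4 strains, with points for libraries, bars for means and whiskers for SD (n = 3), the lower vit-6 whisker of the double mutant ending at 0. The trx-2 and ldh-1 points of both strains with the nuo-6 mutation lie above those of N2 and itr-1.

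The third comparison, double mutant against nuo-6 mutant, asks what the itr-1 mutation changes in animals whose complex I is already impaired, the question of the study's title. Genes of complex I, the mitochondrial ribosome and muscle were lower in the double mutant, and single genes such as lys-4, asp-6 and nhx-2 were higher. The complex I gene ndub-3 (WBGene00007684, chromosome II, 8964242 to 8964890) fell from 513 ± 14.7 to 387 ± 6.6 TPM, a log2 fold of -0.41 ± 0.04 (SE, n = 3 per group, adjusted p = 1.86e-04). The mitochondrial ribosomal protein gene mrps-14 (WBGene00011334, chromosome II, 10240277 to 10242490) fell from 179 ± 4.57 to 114 ± 1.47 TPM (-0.65 ± 0.04, adjusted p = 6.77e-06). The troponin T gene tnt-2 (WBGene00006587, chromosome X, 8721546 to 8723550) fell from 920 ± 23.1 to 637 ± 10.6 TPM (-0.53 ± 0.04, adjusted p = 1.01e-05). The lysozyme gene lys-4 (WBGene00003093, chromosome IV, 11621429 to 11623174) rose from 62.6 ± 4.93 to 258 ± 44.2 TPM (2.02 ± 0.14, adjusted p = 1.02e-05). In all, 2353 genes (15.4%) changed, 1522 up and 831 down, with no overlap between libraries in 6038 of the 15230 tested, where chance gives 10%. Median-of-ratios scaling gave 881 rises and 1137 falls, and quantile normalization 1068 and 1025. The count was 1378 without nuo-6 replicate 2, 1144 without nuo-6 replicate 3, 1234 without double-mutant replicate 1 and 1380 without double-mutant replicate 3, against 7848 with array weights.

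Of 35 nuclear complex I genes, 0 rose and 33 fell (0 and 34 adjusted over the list alone). The shift was -0.35 against a median of all genes of 0.07 (camera adjusted p = 8.76e-31, adjusted p = 0.047 with an estimated correlation). The mitochondrial ribosome list counted 50 falls and 0 rises among 70 (0 and 60 adjusted over the list alone, shift -0.33, camera adjusted p = 8.76e-31, adjusted p = 0.047 with an estimated correlation), and muscle sarcomere genes 31 falls and 0 rises among 49 (0 and 33 adjusted over the list alone, shift -0.33, camera adjusted p = 1.25e-23, adjusted p = 0.0166 with an estimated correlation). These 3 calls are the only list calls of the 5 comparisons that held with an estimated correlation. The myosin light chain gene mlc-1 fell by 0.47 ± 0.04, the troponin C gene pat-10 by 0.57 ± 0.05 and alp-1, a protein of the sarcomere's Z-disc analogue, by 0.59 ± 0.05. Nuclear genes of complexes II to V fell in 24 of 39 cases (0 and 32 adjusted over the list alone, shift -0.27, camera adjusted p = 2.83e-20, adjusted p = 0.107 with an estimated correlation), and mtDNA genes in 3 of 12 (0 and 9 adjusted over the list alone, shift -0.39, camera adjusted p = 1.39e-05, adjusted p = 0.417 with an estimated correlation). The gene mt-ND3 was at -0.55 ± 0.09. TCA and glyoxylate cycle genes fell in 8 of 25 cases (0 and 8 adjusted over the list alone, shift -0.14, camera adjusted p = 2.39e-05, adjusted p = 0.417 with an estimated correlation), a call lost with quantile normalization (adjusted p = 0.0695, the highest of 4.72e-09 to 0.0695). The succinyl-CoA ligase genes sucg-1 and sucl-2 fell by 0.53 ± 0.07 and 0.45 ± 0.07.

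Autophagy and lysosome genes rose in 10 of 46 cases and fell in 0 (16 and 0 adjusted over the list alone, shift 0.13, camera adjusted p = 5.3e-07, adjusted p = 0.417 with an estimated correlation). The aspartyl protease gene asp-6 went from 1220 ± 22.9 to 2500 ± 291 TPM (1.02 ± 0.10) and asp-3 rose by 0.89 ± 0.09. Intestinal genes rose in 12 of 29 cases (20 and 0 adjusted over the list alone, 8 and 0 with median-of-ratios scaling, shift 0.24, camera adjusted p = 2.58e-05, adjusted p = 0.417 with an estimated correlation). The sodium-proton exchanger gene nhx-2 was at 0.55 ± 0.08. Innate immunity genes counted 31 rises and 14 falls among 85 (35 and 14 adjusted over the list alone, shift 0.25, camera adjusted p = 0.0158, adjusted p = 0.58 with an estimated correlation), and without double-mutant replicate 3 the adjusted p was 0.112, the highest of 0.00104 to 0.112. They included the saposin-like gene spp-9 at 4.26 ± 0.20 and clec-60 at 3.23 ± 0.19. Among genes of InsP3 and calcium signalling, 3 rose and 2 fell of 42 (3 and 2 adjusted over the list alone, 1 and 2 with median-of-ratios scaling, camera adjusted p = 0.194, adjusted p = 0.707 with an estimated correlation); without double-mutant replicate 2 the list passed at 0.0431, the lowest of 0.0431 to 0.71, and without all libraries numbered 2 at 0.0468. In that list csq-1 fell by 0.37 ± 0.05 and crt-1, which encodes the reticulum's calcium-binding calreticulin, rose from 1220 ± 75.4 to 1680 ± 143 TPM (0.46 ± 0.07). Of the other lists tied to the study's title, non-muscle actomyosin counted 7 rises and 1 fall among 58, or 0 and 4 with median-of-ratios scaling (9 and 1 adjusted over the list alone, shift 0.055, camera adjusted p = 0.0185, adjusted p = 0.58 with an estimated correlation). That call was lost with median-of-ratios scaling (adjusted p = 0.107), without nuo-6 replicate 2 (0.0694) or double-mutant replicate 2 (0.0534), of 0.00394 to 0.107 over 22 alternatives, and without all libraries numbered 2 (0.137). Mitochondrial dynamics and mitophagy, with 1 rise and 3 falls among 22, did not pass (1 and 3 adjusted over the list alone, camera adjusted p = 0.244, adjusted p = 0.58 with an estimated correlation). The cysteine synthase-like gene cysl-2 rose from 173 ± 30.3 to 399 ± 58.7 TPM (1.21 ± 0.12), and gmd-2, a GDP-mannose dehydratase gene, fell from 57.8 ± 7.01 to 1.95 ± 1.68 TPM (-4.46 ± 0.30). In the nuo-6 libraries gmd-2 was also higher than in any library of the other strains.

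The UPRmt list counted 2 rises and 4 falls among 24 (2 and 6 adjusted over the list alone, 1 and 7 with median-of-ratios scaling, shift -0.16, camera adjusted p = 0.00184, adjusted p = 0.417 with an estimated correlation). The import receptor gene tomm-20 was at -0.45 ± 0.05. That call was lost without double-mutant replicate 2 and with quantile normalization, where camera's adjusted p ranged from 9.66e-05 to 0.055 over 22 alternatives, and without all libraries numbered 2 (adjusted p = 0.0685). Heat shock genes counted 1 rise and 0 falls among 25 (0 and 0 adjusted over the list alone, camera adjusted p = 0.839, adjusted p = 0.965 with an estimated correlation). Cytosolic ribosome genes counted 29 rises and 1 fall (36 and 2 adjusted over the list alone, camera adjusted p = 1.32e-05, adjusted p = 0.58 with an estimated correlation), but 0 and 2 with median-of-ratios scaling, where the call was lost (adjusted p = 0.156, the highest of 1e-09 to 0.156). Cuticle collagen genes fell in 38 of 135 cases and rose in 4 (4 and 45 adjusted over the list alone, shift -0.43, camera adjusted p = 3.23e-14, adjusted p = 0.173 with an estimated correlation). The gene col-149 was at -1.19 ± 0.11. Of the 6 vitellogenin genes, which encode yolk proteins and share near-identical copies, 2 fell (6 adjusted over the list alone, shift -3.06, camera adjusted p = 2.26e-04, adjusted p = 0.417 with an estimated correlation). Yolk gene levels varied between libraries of one strain, as for vit-6 at 313, 32.6 and 32.8 TPM in double-mutant replicates 2, 1 and 3. The fold of vit-4 was -3.78 ± 1.02 (adjusted p = 0.0294), and its call was lost without nuo-6 replicate 2 or 3 or double-mutant replicate 1 or 3, with an adjusted p of up to 0.114.

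The fourth comparison, double mutant against itr-1 mutant, asks what impaired complex I changes when the InsP3 receptor is impaired too. Genes of the UPRmt, glycolysis, oxidative stress and detoxification were higher in the double mutant, and ribosomal protein, proteasome and sperm genes were lower. These list calls did not hold with an estimated correlation (adjusted p = 0.0659 to 0.511). The gene trx-2 rose from 91 ± 3.18 to 178 ± 8.49 TPM, a log2 fold of 0.96 ± 0.05 (SE, n = 3 per group, adjusted p = 5.35e-07), ldh-1 from 62.2 ± 2.53 to 163 ± 2.37 TPM (1.38 ± 0.05, adjusted p = 7.03e-08) and sod-3 from 3.61 ± 0.414 TPM by 1.92 ± 0.09 (adjusted p = 3.02e-07). The largest rise was in cyp-14A4 at 5.09 ± 0.15 and the largest fall in ilys-5, from 327 ± 22.4 to 10.5 ± 5.66 TPM (-4.96 ± 0.32), among the genes the naming rule admits. In all, 6964 genes (45.7%) changed, 4463 up and 2501 down, with no overlap between libraries in 7818 of the 15230 tested, where chance gives 10%. Median-of-ratios scaling gave 3390 rises and 3316 falls, and quantile normalization 3241 and 3582.

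Of 24 UPRmt genes, 18 rose and 0 fell (18 and 0 adjusted over the list alone, shift 0.34 against a median of all genes of 0.09, camera adjusted p = 9.64e-07, adjusted p = 0.298 with an estimated correlation). Glycolysis and gluconeogenesis counted 19 rises and 2 falls among 24 (19 and 2 adjusted over the list alone, shift 0.46, camera adjusted p = 9.64e-07, adjusted p = 0.374 with an estimated correlation). The gene aldo-1 was at 1.58 ± 0.06. Oxidative stress and SKN-1 target genes rose in 26 of 31 cases and fell in 0 (28 and 0 adjusted over the list alone, shift 0.55, camera adjusted p = 9.92e-08, adjusted p = 0.0659 with an estimated correlation). The thioredoxin reductase gene trxr-2 was at 1.09 ± 0.08. HIF-1 targets counted 10 rises and 1 fall among 16 (11 and 1 adjusted over the list alone, shift 0.41, camera adjusted p = 2.85e-04, adjusted p = 0.265 with an estimated correlation), among them ldh-1 and cysl-2 at 2.66 ± 0.12. Detoxification genes counted 106 rises and 16 falls among 176 (111 and 16 adjusted over the list alone, shift 0.47, camera adjusted p = 6.64e-08, adjusted p = 0.265 with an estimated correlation). Genes of mtDNA rose in 9 of 12 cases (9 and 0 adjusted over the list alone, shift 0.52, camera adjusted p = 4.83e-04, adjusted p = 0.511 with an estimated correlation), as mt-COX1 did from 2560 ± 180 to 5080 ± 42.5 TPM. Mitochondrial dynamics and mitophagy genes rose in 14 of 22 cases (15 and 2 adjusted over the list alone, shift 0.20, camera adjusted p = 0.00529, adjusted p = 0.305 with an estimated correlation). The gene sqst-1 was at 1.38 ± 0.13 and drp-1 at 0.50 ± 0.06.

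Cytosolic ribosomal protein genes fell in 57 of 81 cases (0 and 64 adjusted over the list alone, shift -0.26, camera adjusted p = 2.17e-18, adjusted p = 0.319 with an estimated correlation), and proteasome genes in 27 of 33 (0 and 32 adjusted over the list alone, shift -0.34, camera adjusted p = 6.78e-14, adjusted p = 0.322 with an estimated correlation). Muscle sarcomere genes counted 3 rises and 24 falls among 49 (3 and 25 adjusted over the list alone, shift -0.21, camera adjusted p = 9.64e-07, adjusted p = 0.265 with an estimated correlation). The troponin T gene mup-2 was at -0.59 ± 0.04 and the troponin I gene tni-1 at -0.60 ± 0.07. Sperm genes counted 2 rises and 58 falls among 80 (2 and 64 adjusted over the list alone, shift -0.96, camera adjusted p = 2.83e-14, adjusted p = 0.511 with an estimated correlation), beside stage scores of 4.79 to 5.90 in itr-1 and 4.38 to 5.65 in the double mutant. All 6 vitellogenin genes fell (6 adjusted over the list alone, shift -3.54, camera adjusted p = 0.00162, adjusted p = 0.511 with an estimated correlation). The gene vit-3 was at -4.70 ± 0.89 and values of near-identical copies uncertain.

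The fifth comparison asks whether the nuo-6 effect differs between animals with and without the itr-1 mutation, as the interaction of both mutations on the log2 scale, where a negative value means that the nuo-6 effect was lower in the itr-1 background. Between both backgrounds, which share no library, the nuo-6 effects had r = 0.574 and rho = 0.582 across the 15230 genes, which are not independent replicates, and 74.6% of genes had the same sign. Of the 7968 genes changed by nuo-6 in the N2 background, 87.1% had the same sign in the itr-1 background, and those that rose had a median of 0.60 in the former and 0.36 in the latter. Genes that rose in the itr-1 background had a median of 0.53 there and 0.50 in the N2 background, and choosing genes in one background inflates their folds there. For falls the medians differed from both sides. Genes that fell in the itr-1 background had -0.57 there and -0.29 in the N2 background. Those that fell in the N2 background had -0.48 there and -0.26 in the itr-1 background. The stress genes trx-2 and ldh-1 are examples of rises in both, at 0.99 ± 0.05 and 1.44 ± 0.05 without and 0.96 ± 0.05 and 1.38 ± 0.05 with the itr-1 mutation. Genes called in both backgrounds in the same direction numbered 4675, with 3418 rises where independent lists give 1663.3 and 1257 falls where they give 376.4, and 175 were called in opposite directions. The itr-1 effects with and without the nuo-6 mutation had r = 0.274 and rho = 0.290, and 66.9% of genes had the same sign.

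The interaction passed for 1829 genes, 562 positive and 1267 negative, or 876 and 1184 with median-of-ratios scaling and 1073 and 995 with quantile normalization. Negative interactions included 59 collagen and 40 sperm genes, and positive ones 8 genes of the unfolded protein response of the endoplasmic reticulum and 6 one-carbon and propionate genes. The calls of these lists did not hold with an estimated correlation (adjusted p = 0.26 to 0.588). The glutathione S-transferase gene gst-4 had an interaction of 1.15 ± 0.18 (SE, n = 3 per group, adjusted p = 0.00326), with 136 ± 17.7 TPM in N2, 36.5 ± 5.05 in itr-1, 191 ± 28 in nuo-6 and 115 ± 8.69 in the double mutant. The cysteine synthase-like gene cysl-2 was at 1.56 ± 0.18 (adjusted p = 4.03e-04), mrps-14 at -0.48 ± 0.06 (adjusted p = 7.96e-04) and lys-4 at 1.47 ± 0.20 (adjusted p = 0.0013). The Skp1-related gene skr-17 (WBGene00004823, chromosome II, 7783517 to 7784654) was at 1.21 ± 0.293 TPM in itr-1 and 18.9 to 21.8 in the other strains (3.35 ± 0.18). The count was 945 without N2 replicate 1, 1133 without N2 replicate 3, 1218 without itr-1 replicate 2, 867 without nuo-6 replicate 2, 909 without nuo-6 replicate 3 and 1046 without double-mutant replicate 1. It was 792 with the stage score as a covariate, chosen after the data were seen, and 3936 with array weights.

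Cuticle collagens counted 6 positive and 59 negative interactions among 135 (14 and 66 adjusted over the list alone, shift -0.57 against a median of all genes of -0.05, camera adjusted p = 1.96e-06, adjusted p = 0.513 with an estimated correlation). Collagen gene col-92, of a family with similar copies, stood at 327 TPM in N2 and 1100, 1340 and 1070 in itr-1, nuo-6 and the double mutant (-2.08 ± 0.18). Sperm genes counted 1 positive and 40 negative among 80 (2 and 58 adjusted over the list alone, shift -1.25, camera adjusted p = 1.98e-11, adjusted p = 0.588 with an estimated correlation), beside the low stage score of N2. Genes of the unfolded protein response of the endoplasmic reticulum had 8 positive and 0 negative among 28 (11 and 0 adjusted over the list alone, shift 0.23, camera adjusted p = 7.37e-06, adjusted p = 0.26 with an estimated correlation). The disulfide isomerase gene pdi-3 was at 0.50 ± 0.07. One-carbon and propionate genes had 6 positive and 0 negative among 25 (10 and 1 adjusted over the list alone, shift 0.20, camera adjusted p = 1.5e-04, adjusted p = 0.26 with an estimated correlation). The dehydrogenase gene alh-8 was at 0.55 ± 0.08. The complex I list shifted by -0.10 (camera adjusted p = 7.34e-06, adjusted p = 0.513 with an estimated correlation) with 3 negative genes of 35 (3 adjusted over the list alone, 0 with median-of-ratios scaling). These were ndus-8, whose call was lost without nuo-6 replicate 2 (adjusted p = 0.0545), lpd-5, lost without N2 replicate 1 or 2, itr-1 replicate 2 or 3, nuo-6 replicate 2 or 3 or double-mutant replicate 3 (0.0517 to 0.0904), and nduf-6, lost without N2 replicate 1 or 3, itr-1 replicate 2 or 3, any nuo-6 library or double-mutant replicate 1 (0.0525 to 0.0902). All 3 calls were also lost with median-of-ratios scaling, quantile normalization and eBayes without trend, with an adjusted p of up to 0.129, 0.212 and 0.233. The mitochondrial ribosome list shifted by -0.12 (camera adjusted p = 1.12e-05, adjusted p = 0.513 with an estimated correlation) with 6 negative genes of 70 (6 adjusted over the list alone, 1 with median-of-ratios scaling). The UPRmt list did not pass (camera adjusted p = 0.141, adjusted p = 0.759 with an estimated correlation). It passed downward with the stage score as a covariate (adjusted p = 0.00744, median -0.13, against 0.0558 to 0.52 over 22 alternatives). The non-muscle actomyosin list did not pass (camera adjusted p = 0.847, adjusted p = 0.958 with an estimated correlation). In it the myosin heavy chain gene nmy-1 was at -0.69 ± 0.19 (adjusted p = 0.0367), a call lost in 9 of 22 alternatives with an adjusted p of up to 0.0884, among them the omission of N2 replicate 1 or 3, itr-1 replicate 1 or 2, any nuo-6 library or double-mutant replicate 1.

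**Figure D3:**
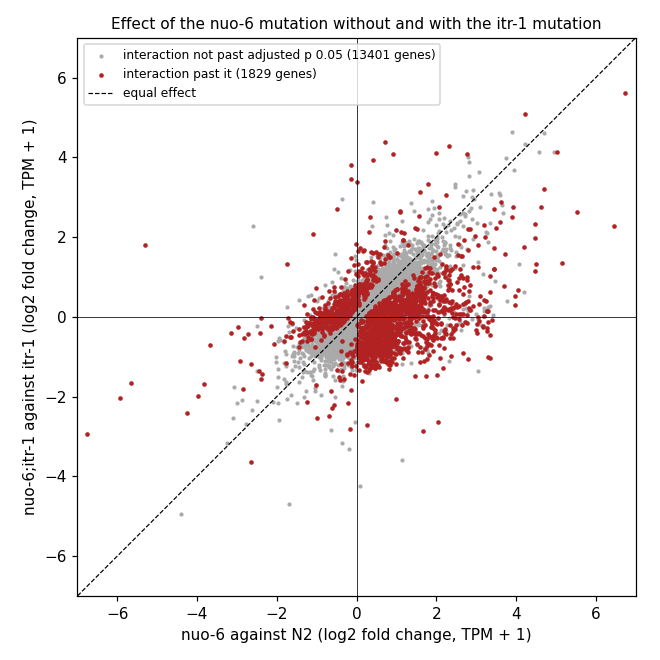
Log2 fold of nuo-6 against N2 (x axis) and of the double mutant against itr-1 (y axis) for the 15230 genes tested, with the dashed line at equal effects. The 1829 red points passed the interaction test and the grey points did not.

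**Figure D4:**
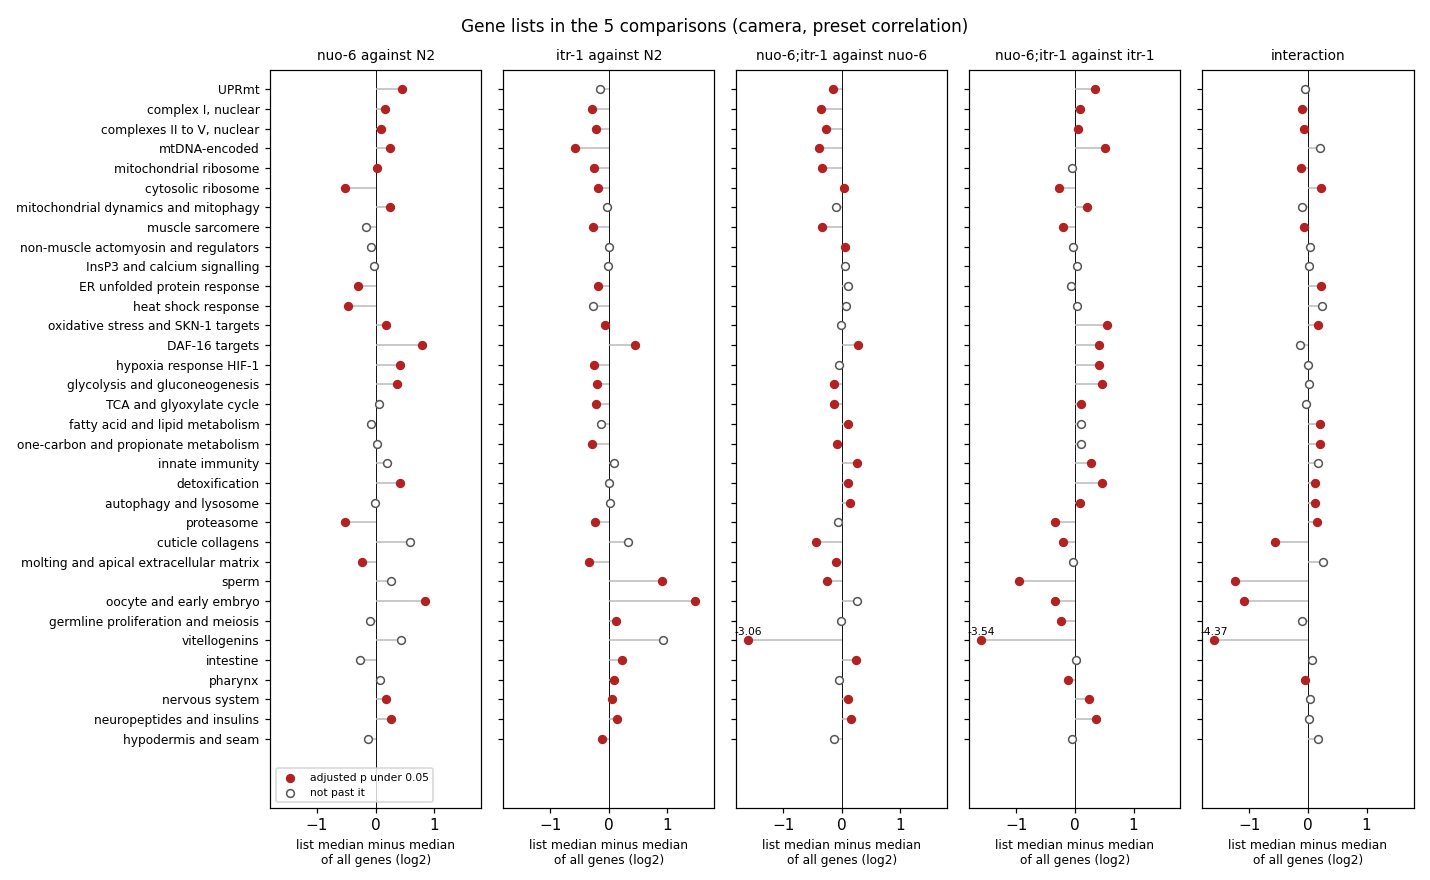
Median log2 fold of 34 gene lists minus the median of all genes (x axis) in the 5 comparisons, filled where camera's adjusted p was under 0.05 with the preset correlation. The vitellogenin points of -3.06, -3.54 and -4.37 lie beyond the axis and are drawn at its edge.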

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

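Chosen only after the result was seen were the shuffled residuals, the correlations with the stage slope, the yolk gene test, the 3 tests of the chromosome IV stretch, the re-closing of TPM and the stage score itself. The genes and lists below stand out because the nuo-6 effect differed between the itr-1 and the N2 background by the interaction test. It passed for 1829 genes, and 2 of 100 regroupings of the 12 libraries, the real one included, gave as many, the other with 2506 genes. Such regroupings mix strains, whose other differences widen the spread, so they decide nothing about the interaction. With the effects of both mutations removed first and only the residuals shuffled, 2 of 100 again gave as many, the real one included, the other with 1836 genes. This share under 0.05 argues against chance without excluding it, since 1 shuffle exceeded the real count and the test was chosen after the result. Shuffling also treats the residuals as exchangeable, while those of the libraries numbered 2 correlated with each other (0.118 to 0.506). In each of the 4 comparisons of 3 against 3 libraries, 1 of 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. There the real counts were 7968, 6109, 2353 and 6964 and the highest of the other splits 0, 0, 2 and 1, for nuo-6 against N2, itr-1 against N2, and the double mutant against nuo-6 and itr-1. Each of the other splits also mixes both strains in its groups, which widens the spread. Their low counts were therefore to be foreseen and lend the real counts no support.

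The 5 largest positive interactions among named genes were msp-19 at 3.67, skr-17 at 3.35, the receptor gene frpr-5 at 3.17, the GTPase gene rab-11.2 at 3.16 and the chemoreceptor-like gene srw-85 at 3.08. Those of frpr-5 and rab-11.2 were lost in 6 and 1 of 22 alternatives, with an adjusted p of up to 0.0694 and 0.0663. For frpr-5 these were the omission of N2 replicate 1 or 2, itr-1 replicate 2 or 3, or double-mutant replicate 1 or 3 (adjusted p = 0.0694, 0.0517, 0.06, 0.0537, 0.0608 and 0.0562, within 0.0119 to 0.0694 over all), and for rab-11.2 the pseudocount of 0.1. The 5 largest negative ones were vit-2 at -4.69, vit-6 at -4.52, col-7 at -4.38, col-62 at -4.32 and nspb-2 at -3.46. Both yolk gene calls, in a family that holds some near-identical copies, were lost in 13 of 22 alternatives, among them the omission of any library except N2 replicate 2 and double-mutant replicate 2, with an adjusted p of 0.0523 to 0.107 for vit-2 and 0.0544 to 0.11 for vit-6 without those libraries. With the stage score as a covariate the calls of frpr-5, rab-11.2, vit-2 and vit-6 were lost, as were those of the vitellogenin, oxidative stress, fatty acid, detoxification and autophagy lists. The call of the oocyte list, from which the score is made, was lost by that construction. Lists with a median interaction below 0 and a camera call were complex I at -0.16, complexes II to V at -0.12, mitochondrial ribosome at -0.17, muscle sarcomere at -0.13, cuticle collagens at -0.62, sperm at -1.30, oocyte and early embryo at -1.14, vitellogenins at -4.43 and pharynx at -0.10. Lists above 0 were cytosolic ribosome at 0.17, unfolded protein response of the endoplasmic reticulum at 0.18, oxidative stress and SKN-1 targets at 0.13, fatty acid and lipid metabolism at 0.15, one-carbon and propionate metabolism at 0.14, detoxification at 0.073, autophagy and lysosome at 0.067 and proteasome at 0.095. The calls of complexes II to V, muscle sarcomere and detoxification were lost with median-of-ratios scaling, those of complexes II to V and cytosolic ribosome with quantile normalization, and that of detoxification also without itr-1 replicate 1 (adjusted p = 0.0516) or double-mutant replicate 3 (adjusted p = 0.0696), of 8.33e-04 to 0.116 over its alternatives. Re-closing TPM ended those of complexes II to V and detoxification. None of these list calls held with an estimated correlation, where adjusted p was 0.26 or higher.

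The moulting and sperm lists passed in itr-1 against N2 (adjusted p = 0.71 and 0.731 with an estimated correlation), and the collagen, sperm and vitellogenin lists in the interaction (adjusted p = 0.513, 0.588 and 0.588 with an estimated correlation). A candidate explanation is that the N2 libraries were taken at an earlier point of the fourth larval stage, since over the 290 tested genes of these 4 lists, chosen after their results were seen, folds followed each gene's slope on the stage score within strains, with r = 0.564 for itr-1 against N2, 0.532 for nuo-6 against N2 and -0.788 for the interaction (0.406, 0.183 and -0.552 over all 15230 genes), across genes that are not independent replicates. In the double mutant against nuo-6, which holds no N2 library, r was -0.666 over the 290 genes, which an early N2 leaves unexplained. With the stage score as a covariate the UPRmt list kept a median of 0.61 and its call in nuo-6 against N2. The slope on the score comes from differences within strains, while the scores of N2 (3.34 to 4.17) and nuo-6 (4.56 to 4.78) do not overlap. The adjustment therefore extrapolates and cannot decide whether an early N2 is the whole cause of the UPRmt rise. With an estimated correlation and no covariate that call was lost (adjusted p = 0.295). In the double mutant against nuo-6, complex I kept -0.26 and the vitellogenins -3.73, with their calls. The vitellogenin call was lost with an estimated correlation and no covariate (adjusted p = 0.417). These values cannot decide about a stage difference between those strains. The score was 4.56 to 4.78 in nuo-6 and 4.38 to 5.65 in the double mutant. Adjustment for it deepened the vitellogenin median from -2.99, and it cannot remove a stage difference that oocyte genes do not show. With r = -0.666 there, such a difference stays open. Also open is whether the sampling or the mutations themselves set the stage, since the rate of development by genotype was not analysed here.

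In the itr-1 libraries 4 neighbouring genes of chromosome IV, msp-19 among them, were low, and 3 of them were listed at 0. The same genes had a median of -0.16 in the double mutant against nuo-6, so they were not low in the other strain with the itr-1 mutation. They were chosen as low in itr-1 libraries only, so this value follows from the choice. It is no separate test of the itr-1 mutation as the cause. Reads shared among major sperm protein copies are argued against, since 3 genes at 0 in all itr-1 libraries lie outside that family, while 29 other major sperm protein genes had a median of 1.43 in itr-1 against N2. Of 7 genes low in itr-1 libraries only, 4 lay within 20 kb, as in few of 10000 random gene sets (share 1e-04, the smallest these sets can give), but this clustering was seen before it was tested and cannot decide the cause. A variant of the itr-1 strain that the double mutant lacks stays open and untested by genome sequence, and a deletion of the whole stretch would also have removed the pseudogene WBGene00003445 inside it, which was at 1.21 in itr-1 against N2, unless its reads came from other copies.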

How the results depend on the processing

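Chosen only after the data were seen were the omission of all libraries numbered 2, the re-closing of TPM and the stage score as a covariate. Counts of changed genes are given in the order nuo-6 against N2, itr-1 against N2, double mutant against nuo-6, double mutant against itr-1 and interaction. A fold minimum of 2 left 1574, 1196, 269, 964 and 836 genes, by its own construction. Array weights gave 7848 in the third and 3936 in the interaction, and the stage score as a covariate gave 1964 in itr-1 against N2, 3858 in the third and 792 in the interaction, with a correlation of 0.708 between the nuo-6 effects in both backgrounds; the cause was not tested. Without one library each, counts ranged from 6715 to 8299, 4138 to 6457, 1144 to 2634, 5477 to 7121 and 867 to 2627, the correlation from 0.516 to 0.629, and the median folds of genes called in one background from 0.321 to 0.373 and 0.392 to 0.474 in the other, with fewer samples. Counts stayed within 1.5 times under pseudocounts, filters, median-of-ratios scaling, quantile normalization, eBayes options and the fit of only the groups compared. Without the libraries numbered 2 they were 7263, 4781, 1843, 6139 and 1529, and after re-closing 7414, 6129, 2688, 6704 and 1903.

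Of 106 called list tests, 87 held with median-of-ratios scaling, 85 with quantile normalization, 99 with the filter of 5 TPM and 77 with the stage score, and over all omissions of one library 1189 of 1272 held. Of 622 called named genes, 586 held with median-of-ratios scaling, 584 with quantile normalization and 532 with the stage score. With the stage score camera's direction, the list against all other genes, turned for oocyte genes in nuo-6 against N2 (median -0.014) and the interaction (0.01). In itr-1 against N2 it turned for cytosolic ribosome (median 0.049), moulting (0.16), sperm (0.094), oocyte (-0.007), germline (-0.15) and hypodermis genes (0.16). Quantile normalization turned cytosolic ribosome in itr-1 against N2 (median 0.027). The score is the mean of the oocyte genes, so their small medians follow from the adjustment. Tests of that list with the stage score therefore decide nothing. For the other turns the cause was not tested.

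The replicate block gave 8633, 6873, 2809, 7470 and 2762 genes and kept 96 of 106 list calls, not that of HIF-1 targets in nuo-6 against N2 (adjusted p = 0.0578, the highest of 0.0046 to 0.0578). Of 18 pairs of libraries with the same number in different strains, 11 correlated above 0.1 in their deviations from the group means (-0.02 to 0.506, the other 36 pairs -0.474 to 0.293). The main model did not pair the libraries by number, a choice that these values do not settle. All 6 pairs of libraries numbered 2 lay above 0.1, at 0.118 to 0.506, and these had the highest stage score of each strain. In 22 of 36 comparisons a library correlated best with its own number, more often than an arbitrary pick among a strain's 3 libraries would give. For 4 libraries this held in all of their comparisons. An effect shared by libraries of the same number, clearest for those numbered 2, is thus not excluded, and the main model leaves it out. The depth is unknown, so no limit on low genes can be given, and genes near 1 TPM depend on the pseudocount.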

Other observations

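Chosen only after the data were seen were the stage score, the search for genes high or low in one strain and the re-closing of TPM without ribosomal protein genes, whose bounds were set before its result. The neuronal lists passed upward with the nuo-6 mutation in both backgrounds and also in itr-1 against N2. Of nervous system genes in nuo-6 against N2, 41 rose and 1 fell of 63 (42 and 1 adjusted over the list alone, 24 and 4 with median-of-ratios scaling, shift 0.18, camera adjusted p = 0.00153, adjusted p = 0.741 with an estimated correlation), with the synaptobrevin gene snb-1 at 0.54 ± 0.05. In the double mutant against itr-1, 36 rose and 1 fell of 63 (39 and 1 adjusted over the list alone, 25 and 1 with median-of-ratios scaling, shift 0.24, camera adjusted p = 1.37e-05, adjusted p = 0.552 with an estimated correlation). In the double mutant against nuo-6, 15 rose and 1 fell of 63 (21 and 1 adjusted over the list alone, 7 and 1 with median-of-ratios scaling, shift 0.10, camera adjusted p = 5.69e-04, adjusted p = 0.58 with an estimated correlation). In itr-1 against N2, 27 rose and 3 fell of 63 (29 and 4 adjusted over the list alone, 12 and 5 with median-of-ratios scaling, shift 0.06, camera adjusted p = 0.0318, adjusted p = 0.741 with an estimated correlation). That call was lost with median-of-ratios scaling or quantile normalization, after re-closing TPM (adjusted p = 0.054) and without N2 replicate 2 (0.134) or itr-1 replicate 3 (0.329), of 8.57e-04 to 0.329 over 22 alternatives. Of neuropeptide and insulin genes, 78 rose and 3 fell of 127 (81 and 3 adjusted over the list alone, 54 and 7 with median-of-ratios scaling, shift 0.25, camera adjusted p = 1.47e-04, adjusted p = 0.565 with an estimated correlation) in nuo-6 against N2, with the FMRFamide-like peptide gene flp-3 at 1.09 ± 0.10 and nlp-27, a neuropeptide-like gene, at 2.18 ± 0.15. In the double mutant against itr-1 the counts were 82 rises and 5 falls (89 and 6 adjusted over the list alone, 61 and 6 with median-of-ratios scaling, shift 0.36, camera adjusted p = 9.64e-07, adjusted p = 0.375 with an estimated correlation), with the insulin-like gene ins-4 at 0.95 ± 0.11, and against nuo-6 they were 25 and 3 (42 and 3 adjusted over the list alone, 12 and 3 with median-of-ratios scaling, shift 0.16, camera adjusted p = 1.84e-04, adjusted p = 0.528 with an estimated correlation), with flp-33 at 0.76 ± 0.10. In itr-1 against N2 they were 55 and 4 (57 and 6 adjusted over the list alone, 28 and 10 with median-of-ratios scaling, shift 0.14, camera adjusted p = 0.00989, adjusted p = 0.71 with an estimated correlation), a call lost without itr-1 replicate 3 (adjusted p = 0.122, the highest of 4.12e-04 to 0.122). Neither list passed the interaction test (camera adjusted p = 0.651 and 0.87, adjusted p = 0.958 for both with an estimated correlation). Both passed there downward with the stage score as a covariate (adjusted p = 3.27e-05 and 1.48e-04, medians -0.18 and -0.17, against 0.0562 to 0.977 and 0.181 to 0.996 over the alternatives).

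Pharynx genes counted 1 positive and 22 negative interactions among 80 (3 and 27 adjusted over the list alone, shift -0.05, camera adjusted p = 4.65e-04, adjusted p = 0.513 with an estimated correlation), with abu-6 at -2.83 ± 0.14, a gene with near-identical copies. In itr-1 against N2, 38 rose and 8 fell of 80 (41 and 11 adjusted over the list alone, shift 0.09, camera adjusted p = 0.00468, adjusted p = 0.605 with an estimated correlation), or 30 and 16 with median-of-ratios scaling. Of germline proliferation and meiosis genes in the double mutant against itr-1, 1 rose and 8 fell of 44 (1 and 5 adjusted over the list alone, 1 and 15 with median-of-ratios scaling, shift -0.24, camera adjusted p = 3.42e-04, adjusted p = 0.631 with an estimated correlation), with glh-4, a helicase of germ granules, at -1.51 ± 0.10. Of hypodermis and seam genes, 8 had a positive and 8 a negative interaction among 56 (12 and 11 adjusted over the list alone, camera adjusted p = 0.444, adjusted p = 0.919 with an estimated correlation).

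A group of 15 genes was higher in all 3 nuo-6 libraries than in any other library by at least 1.5 on the log2 scale. Of these, 6 lay within 20 kb of chromosome V (579277 to 595677), as many as in a share of 1e-04 of 10000 random gene sets, the smallest these sets can give. The search was chosen after the data were seen, so such shares cannot decide a cause. Another run on the same chromosome, 539460 to 553167, holds nhr-155 and lies outside that window. Examples, chosen after their values were seen, are nhr-155, a nuclear receptor gene (chromosome V, 539460 to 541485), at 13.4 ± 2.11 TPM in nuo-6 and 2.70 in the double mutant, and K06H6.1 (chromosome V, 588118 to 589657), at 36.8 ± 5.72 TPM in nuo-6 and 1.76 in the double mutant, against at most 0.243 on average in N2 and itr-1. In N2 libraries 7 genes were higher than in any other library by that margin, among them D1014.7 on chromosome V, at 57.5 ± 1.33 TPM in N2 and 2.86, 0.161 and 0.205 in itr-1, nuo-6 and the double mutant. At most 2 of these genes lay within 20 kb (share of random sets 0.0094). More genes, 45, were lower in N2 libraries than in any other library by that margin, with at most 2 within 20 kb (share 0.3515).

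The nuo-6 and itr-1 effects, both against N2, had r = 0.642 and a covariance of 0.2413 across genes, with the same sign in 75.2%. Unchanged groups against shared controls, simulated 100 times, gave r = 0.496, a covariance of 0.0158 and 66.7%, a difference in covariance of 0.225. The simulated folds had no common shift, while the real median folds of all genes were 0.18 and 0.14 (0.037 and 0.015 with median-of-ratios scaling). Such a shift by itself raises the share of same signs, so the 75.2% cannot be set against the simulated value. Genes that rose in both numbered 2861, where independent lists give 1644.7, and genes that fell in both 978, where they give 255.2. The 3 N2 libraries cannot be split into parts of 2, so part of the excess may come from the shared controls, and without one library each the correlation of the nuo-6 effects in both backgrounds, which share none, was 0.516 to 0.629.

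More genes rose than fell in both single mutants against N2, at 71.2% of changed genes in nuo-6 and 72.2% in itr-1. A candidate explanation is the smaller TPM share of cytosolic ribosomal protein genes in the mutants, since TPM is a share of the library. Re-closed without these genes, TPM gave 59.6% rises in nuo-6 against N2, only just under the bound set for this explanation and still an excess of rises. It gave 69.9% in itr-1 against N2, over the bound that argues against the explanation there. Because the list's share was smaller in nuo-6 libraries, re-closing had to lower the folds of the other genes. The direction of the nuo-6 result was therefore fixed in advance, and only its size was open. With median-of-ratios scaling the shares were 53.2% and 48%, from a scaling that centres the genes' ratios, so the excess of rises depends on the scale in both. Whether the mutants hold more RNA of many genes per animal stays open, since TPM carries no absolute amount and no spike-in values were used here.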
